A study of Brassica rapa subsp. pekinensis with 6 samples.

How the data were processed

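Messenger RNA was measured by sequencing in 6 leaf libraries, 3 from doubled haploid and 3 from autotetraploid Chinese cabbage. Per the labels' protocols, RNA was extracted with TRIzol, its integrity was checked, and libraries were made with a kit for which no strand marking is stated. Per the submitters' processing notes, the tools were Bowtie2 2.2.3, TopHat2 2.0.12, HTSeq 0.6.1 and DESeq 1.18.0. The genome build and annotation were not given in the sources used here.

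The authors deposited 1 table for the whole series. Its labels speak of FPKM, but per the file headers and the values it holds no FPKM. Per the file headers, the authors' signal columns are read counts, and the values show them to be 1 normalised mean per group. The log2 column as deposited equals the log2 ratio of autotetraploid to doubled haploid means, within 5e-05 for genes above 0 in both groups. The p-value and adjusted p-value columns are the authors' own test, and the deposited table holds only genes with an adjusted p-value under 0.05. The product of adjusted p and rank over p was constant, which gave 34980 genes tested. For 95 genes the p-value was deposited as 0. Such a table cannot show genes that did not change, and its selection inflates the changes of genes with low counts.

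The design fixed before the data were examined called for limma and camera on values per library. These could not be run on all genes because the table holds group means. The authors' calls took the place of the planned fit. Gene lists were tested by direction with Fisher's exact test, two-sided, comparing rises and falls in a list with those of the other listed genes that have a description, with Benjamini-Hochberg adjustment over 44 lists of at least 5 genes. The 45 lists, fixed beforehand, were patterns over protein descriptions. A description was present for 10959 genes (82.9%). Genes of a list are not independent, and near-identical copies may share reads, so these p-values are too small to an unknown degree. None of the identifiers matched the reference table of gene names, and no coordinates were used.

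Named genes followed a rule set beforehand, adapted after the deposited table was seen. A mean normalised count of 5 took the place of 5 FPKM, and lists passing Fisher's exact test that of lists passing camera. Genes whose overlap between libraries was not known were kept. The adapted rule took the 10 largest rises and 10 largest falls with a mean of at least 5 in the higher group, leaving out genes whose libraries overlapped where that was known. It also took the 2 genes with the smallest adjusted p in the direction of each list that passed. Gene names are those of the best protein hit, and identifiers are as deposited. Genes at 0 in a group were set to a floor of 3 reads over the group, a mean of 1.02 in autotetraploid and 0.963 in doubled haploid leaves. Genes with 1 or 2 reads kept their own mean, which can lie below this floor, and a floor of 1 read was tried as an alternative after the data were seen. Intervals cover counting error only.

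Each group mean is a sum of whole reads divided by size factors, so the smallest values are steps of 1 read. From these steps the size factors and the reads per library were worked out. In the autotetraploid group 3385 of 3385 values above 0 and under 100 had exactly 1 solution, and in the doubled haploid group 3280 of 3280, within the rounding of the table. With 1 step moved at random by up to 1%, 3.2% and 1.8% of 500 values had any solution. The libraries recovered this way carry no replicate number. limma 3.58.1 in R 4.3.3 was run on log2 of the recovered normalised count plus 1.

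The shift of each chromosome code was estimated by fitting a t distribution, truncated at an absolute log2 fold change of 0.5, to genes with a mean of at least 500. Its interval came from 1000 bootstrap draws of the genes of that code, with the fit to the other codes held fixed. The procedures were tested on simulated data. Reads were recovered for 100% of 598 simulated means, a list made to fall passed in 95% of 20 simulations, and with no effect any list passed in 5% of 20 simulations. The list simulations drew the direction of each gene independently. They therefore do not show how often a list passes without effect when its genes depend on each other. With limma, 96.5% of 200 simulated 4-fold changes among 2590 genes were called. Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 were used. Alternatives covered stricter p limits, a minimum mean, 1 gene per protein hit, Arabidopsis hits only, leaving out A01 genes, and for the recovered reads other pseudocounts, models and left-out libraries.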

Results

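Messenger RNA was sequenced from mature leaves of Chinese cabbage (Brassica rapa subsp. pekinensis), taken from the main stem beneath its lowest branch when the plants bolted. The study compared doubled haploid plants, in which a haploid genome has been doubled, with autotetraploid plants, in which the genome of a single line is present in 4 copies. Both kinds of plant were derived from 1 doubled haploid line and grown alike. Each group had 3 libraries, described by the submitters as biological replicates. The authors' deposited table gave 1 mean normalised read count per gene and group, so the group values have no spread between replicates beside them. It listed 13225 genes, each with an adjusted p under 0.05, and the ratio of adjusted p to p placed the number of genes the authors tested at 34980. Read totals per library were not given in the sources used here. Size factors worked out from the steps between low values ran from 0.926 to 1.01 in the autotetraploid libraries and from 0.917 to 1.12 in the doubled haploid libraries. Over the listed genes the normalised counts summed to 15158622 in autotetraploid and 14534170 in doubled haploid leaves. Small changes were listed only where counts were high. The median change was 5.53-fold for the 1004 genes with a mean under 20 and 1.57-fold for the 3077 genes with a mean of at least 1000.

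The question of the design was which leaf genes differ in expression between the 2 ploidy levels. Genes of photosynthesis, protein synthesis and DNA replication were higher in autotetraploid leaves, and genes of heat shock, abscisic acid, ethylene and the NAC family of transcription factors were lower. Of the genes in the authors' deposited table, 6614 were higher and 6611 lower in autotetraploid leaves. The counts were normalised between libraries, so higher and lower are relative to the other genes, and messenger RNA per cell was not measured. At a change of at least 2-fold the table held 2192 higher and 3044 lower genes. Of all listed genes, 24 were listed at 0 in doubled haploid leaves and 104 at 0 in autotetraploid leaves. The test behind these calls was the authors' own, and genes that did not pass it were not analysed here.

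Among the 10 largest falls was that of a gene whose best protein hit was SAG12, a cysteine protease known from senescing leaves (evm.TU.BraA06000198). Its mean in the authors' deposited table was 4.86 in autotetraploid and 4804 in doubled haploid leaves, a log2 fold change of -9.95. A gene matching xyloglucan endotransglucosylase/hydrolase 18, a cell wall enzyme (Novel00014), had means of 0.720 and 499.6 in the authors' deposited table, and its 2 reads in the lower group put the fall of 694.0-fold within a 95% counting interval of 202 to 6049. A class II small heat shock protein gene (evm.TU.BraA03000538) had means of 0.995 and 339 in the authors' deposited table. Lipoxygenase 3, an enzyme at the start of jasmonate synthesis (evm.TU.BraA08003342), fell from 2559 to 17.3 in the authors' deposited table, a log2 fold change of -7.21. A probable glycerol-3-phosphate acyltransferase gene (evm.TU.BraA03003113) fell from 169 to 1.44 in the authors' deposited table. An uncharacterised gene (Novel00941) was listed at 0 in autotetraploid leaves against 354 in doubled haploid leaves in the authors' deposited table, at least 346-fold lower at a floor of 3 reads over the group. The lower means rested on few reads, with recovered library values of 1.98, 1.01 and 0 for the heat shock gene and of 0, 0 and 4.32 for the acyltransferase gene. The other 4 of the 10 largest falls had no description. The choice and order of the largest changes depended on the floor: with 1 read in place of 3 for genes listed at 0, 14 of the 20 genes chosen were still among them.

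Among the 10 largest rises was that of an arginine decarboxylase 2 gene, whose product starts a route to polyamines (evm.TU.BraA01000386). The authors' deposited table gave it 103 in autotetraploid and 0.299 in doubled haploid leaves, and with 1 read in the lower group the ratio of 345 had a 95% counting interval of 57.2 to 12722. A gene like LBD37, a transcription factor known from nitrogen responses (Novel01412), rose from 2.42 to 336 in the authors' deposited table, a log2 fold change of 7.12. A beta-glucosidase gene whose product frees abscisic acid from its glucose ester (evm.TU.BraA06001927) had means of 55.7 and 0.597 in the authors' deposited table. Endochitinase CH25, a chitin-degrading enzyme (evm.TU.BraA03003788), rose from 1.22 to 98.6, and a GDSL esterase/lipase gene (evm.TU.BraA09005861) rose from 2.55 to 195 in the authors' deposited table. Single libraries weighed on some of the lower means, with recovered library values of 0.896, 0.925 and 5.45 for the gene like LBD37, of 1.79, 0 and 0 for the beta-glucosidase gene and of 0.896, 2.77 and 0 for CH25. The remaining 5 of the 10 largest rises carried no functional description. For evm.TU.BraA10001941, one of these, named here after its values were seen, the autotetraploid mean of 38.5 in the authors' deposited table rested on 2 libraries, with recovered values of 0.988, 75.6 and 38.9 against at most 0.925 in the doubled haploid libraries.

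Photosynthesis genes rose together. Of 81 listed genes of the photosystems and light harvesting, 74 rose and 7 fell (Fisher's exact test against the other described genes, two-sided, adjusted p = 5.88e-14), with a median log2 fold change of 0.72. The gene for the chlorophyll-binding protein CP29.3 (evm.TU.BraA05003802) rose from 4145 to 14637 and that for the photosystem II assembly factor HCF136 (evm.TU.BraA03004636) from 2132 to 5220 in the authors' deposited table. Carbon fixation had 26 rises and 1 fall among 27 genes (Fisher's exact test, adjusted p = 4.49e-06). A Rubisco small chain gene (evm.TU.BraA04001052) rose from 11269 to 54898 and a Rubisco activase gene (evm.TU.BraA04002587) from 76827 to 187379 in the authors' deposited table. In chlorophyll synthesis 15 of 18 genes rose (Fisher's exact test, adjusted p = 0.0257), among them the magnesium chelatase subunits ChlI-2 (evm.TU.BraA06000196, from 2000.2 to 4185) and ChlI-1 (evm.TU.BraA03005149, from 925 to 2068), as means of the authors' deposited table. The chlorophyll list did not pass with 1 gene per protein hit (10 rose and 2 fell, adjusted p = 0.0841) or among genes changed at least 2-fold (4 rose and 1 fell, adjusted p = 0.340, both Fisher's exact test).

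Genes of protein synthesis and DNA replication were also higher in autotetraploid leaves. The list fixed for cytosolic ribosomal proteins took in plastid ones as well, and 247 of its 262 genes rose (Fisher's exact test, adjusted p = 1.44e-54). The parts were alike in direction, with 169 of 180 rising among proteins of the 40S and 60S subunits and 56 of 59 among chloroplast ones. The median change over the whole list was small, at 1.35-fold, but the parts differed in size. In lists added after the data were seen, 190 genes of the 40S and 60S subunits had a median of 1.28-fold, and 7 rose and 1 fell at least 2-fold. For 68 chloroplast ribosomal genes the median was 1.92-fold, and 28 rose and 0 fell at least 2-fold. Genes for the chloroplast proteins S5 (evm.TU.BraA04002238) and L35 (evm.TU.BraA09002140) rose from 1398 to 3967 and from 569 to 1726 in the authors' deposited table. DNA replication genes rose in 16 of 17 cases (Fisher's exact test, adjusted p = 0.00150), with a median of 4.52-fold. Of these genes, 12 had both means under 100, where small changes were seldom listed. All listed genes had a median change of 5.53-fold at a mean under 20 and of 2.40-fold at a mean from 20 to 100. Too few replication genes had a mean of at least 100 for a test, and 66.7% of those few rose. With camera on the genes with recovered reads, 12 DNA replication genes had an adjusted p of 0.000923 with the preset correlation and an adjusted p of 0.332 with an estimated correlation, and 11 ribosomal protein genes 0.0194 and 0.447. The licensing factor MCM3 (evm.TU.BraA06004520) rose from 11.4 to 80.3 and a replication protein A gene (evm.TU.BraA07000611) from 10260.1 to 19949 in the authors' deposited table. Histone genes rose in 25 of 35 cases (Fisher's exact test, adjusted p = 0.0485), including H3.2 (evm.TU.BraA09005846, from 19.8 to 151) and H2B.10 (evm.TU.BraA03001162, from 36.0 to 179), as means of the authors' deposited table. The histone list did not pass with 1 gene per protein hit (adjusted p = 0.848), among genes with a mean of at least 100 (adjusted p = 0.430) or among those with Arabidopsis hits (adjusted p = 0.491, all Fisher's exact test).

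Pathogenesis-related genes, which encode chitinases and other secreted defence proteins, rose in 29 of 39 cases (Fisher's exact test, adjusted p = 0.0133), and 25 of them rose at least 2-fold. Both named genes had the basic chitinase CHB4 as best hit and rose from 569 to 3572 (evm.TU.BraA03002404) and from 242 to 6328 (evm.TU.BraA03002406) in the authors' deposited table. Whether they share reads was not examined, since no gene sequences were used. This list did not pass with 1 gene per protein hit (Fisher's exact test, adjusted p = 0.505) or among genes with Arabidopsis hits (adjusted p = 0.582).

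Heat shock genes were lower in autotetraploid leaves in 48 of 53 cases (Fisher's exact test, adjusted p = 4.59e-09), and 34 fell at least 2-fold. A pair of class I small heat shock protein genes fell from 2154 to 55.4 (evm.TU.BraA05000647) and from 2777 to 84.7 (evm.TU.BraA05000646) in the authors' deposited table. NAC genes fell in 54 of 68 cases (Fisher's exact test, adjusted p = 5.18e-06), with NAC062 (evm.TU.BraA06000721) at a log2 fold change of -2.09 and NAC102 (evm.TU.BraA06003620) at -2.84 in the authors' deposited table. Abscisic acid genes fell in 60 of 85 cases (Fisher's exact test, adjusted p = 0.000734). Those with the smallest p encode abscisic acid 8'-hydroxylase 3, an enzyme of abscisic acid breakdown, and fell from 12625 to 263 (evm.TU.BraA06000244) and from 5524 to 280 (evm.TU.BraA09005587) in the authors' deposited table. Ethylene genes fell in 78 of 119 cases (Fisher's exact test, adjusted p = 0.00293), and 2 genes matching the ethylene response factor ERF109 fell, from 2383 to 135 (evm.TU.BraA03006295) and from 4454 to 268 (evm.TU.BraA01000411) in the authors' deposited table. The abscisic acid list reached an adjusted p of 0.0593 with 1 gene per protein hit, and the ethylene list 0.0547 among genes with a mean of at least 100 (both Fisher's exact test).

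Disease resistance, protein kinase, brassinosteroid and DNA repair genes were lower more often than the other described genes. Resistance genes of the nucleotide-binding kind fell in 30 of 41 cases (Fisher's exact test, adjusted p = 0.0121), with a log2 fold change of -3.66 for a gene matching At4g33300 (evm.TU.BraA01000507) in the authors' deposited table. Protein kinase genes fell in 266 of 451 cases (Fisher's exact test, adjusted p = 0.000566), with -4.11 for CIPK2, a calcium-signalling kinase (evm.TU.BraA10001014), in the authors' deposited table. All 7 listed brassinosteroid genes fell (Fisher's exact test, adjusted p = 0.0257), among them the receptor BRI1 (evm.TU.BraA08002263) at -0.99 in the authors' deposited table. DNA repair genes fell in 11 of 13 cases (Fisher's exact test, adjusted p = 0.0395), with -1.21 for the mismatch repair protein MSH6 (evm.TU.BraA03000480) in the authors' deposited table. Among genes changed at least 2-fold the calls were lost for resistance genes (adjusted p = 0.299) and kinases (41.7% rose, against 41.9% of all listed genes of that size, adjusted p = 0.985, both Fisher's exact test). Without A01 genes they were lost for brassinosteroid (0 rose and 5 fell, adjusted p = 0.0664) and DNA repair (2 rose and 10 fell, adjusted p = 0.0518, both Fisher's exact test). Resistance and DNA repair genes did not pass with 1 gene per protein hit (adjusted p = 0.0593 and 0.135) or among genes with Arabidopsis hits (adjusted p = 0.107 and 0.0557, all Fisher's exact test).

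**Figure D1:**
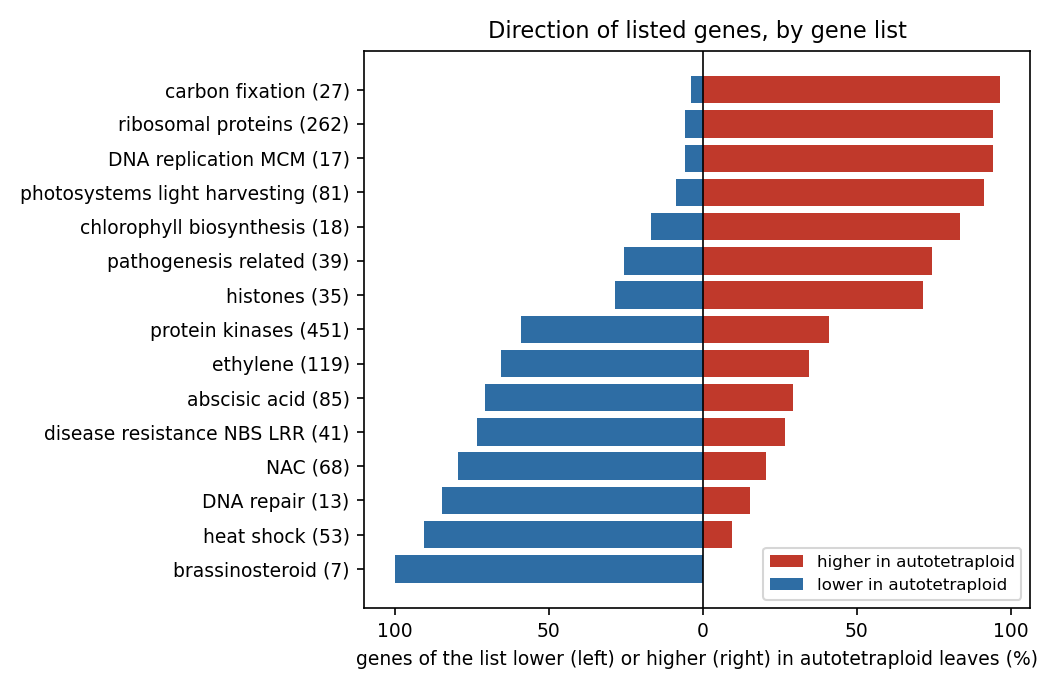
Share of the listed genes of each gene list that were lower (blue, drawn to the left) or higher (red, drawn to the right) in autotetraploid leaves, for the 15 lists that passed, with the number of genes in brackets. The shares that rose run from 0% of 7 brassinosteroid genes to 96.3% of 27 carbon fixation genes.

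The other 29 of the 44 lists tested did not pass. Jasmonate genes were lower in 25 of 37 cases (Fisher's exact test, adjusted p = 0.0897), but passed under 4 of the 6 subsets of genes. Their adjusted p was 0.00686 at an adjusted p limit of 0.001 per gene, 0.0263 at a mean of at least 100, 0.0496 with Arabidopsis hits and 0.0377 without A01 genes (all Fisher's exact test). R2R3 MYB genes were lower in 38 of 61 cases (adjusted p = 0.141), and passed at a mean of at least 100 (adjusted p = 0.0160) and with Arabidopsis hits (adjusted p = 0.0265, all Fisher's exact test). Auxin genes were split into 49 higher and 46 lower genes. Those changed at least 2-fold passed towards rises (59.0% rose, adjusted p = 0.0321) and those with a mean of at least 100 towards falls (31.9% rose, adjusted p = 0.0263, both Fisher's exact test). With camera on 43 auxin genes with recovered reads, the adjusted p towards rises was 0.00980 with the preset correlation and the adjusted p was 0.50 with an estimated correlation. Clock genes rose in 10 of 13 cases (adjusted p = 0.199, Fisher's exact test), and genes with senescence in their description fell in 4 of 7 (adjusted p = 0.863, Fisher's exact test). Cyclin genes were split into 15 rises and 14 falls, and kinesin genes into 14 rises and 12 falls. For tissue other than leaf blade, flower and pollen genes fell in 7 of 9 cases (adjusted p = 0.216, Fisher's exact test) and vascular and lignin genes rose in 16 of 31 cases (adjusted p = 1, Fisher's exact test). Only 4 root genes were listed, too few for a test.

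Genes whose identifiers carry the chromosome code A01 differed in direction from those of every other code. Of 1284 listed A01 genes, 358 rose and 926 fell, so that 27.9% rose (95% Wilson interval 25.5 to 30.4). Over the other 9 codes 52.7% rose (Fisher's exact test, two-sided, adjusted p = 2.02e-64). The same test also passed towards rises for A03 (55.4%, adjusted p = 7.24e-06), A04 (56.8%, adjusted p = 0.000261) and A08 (55.2%, adjusted p = 0.00152). Each of these was set against a remainder that held the A01 genes. The median log2 fold change of the listed genes was -0.53 for A01. The next lowest share was 50.1% (A09) and the highest 56.8% (A04). Along A01, in 10 blocks by identifier number, the share that rose stayed between 22.5% and 34.1%. The code was read from the identifiers, and no map of these identifiers onto a genome was used here.

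**Figure D2:**
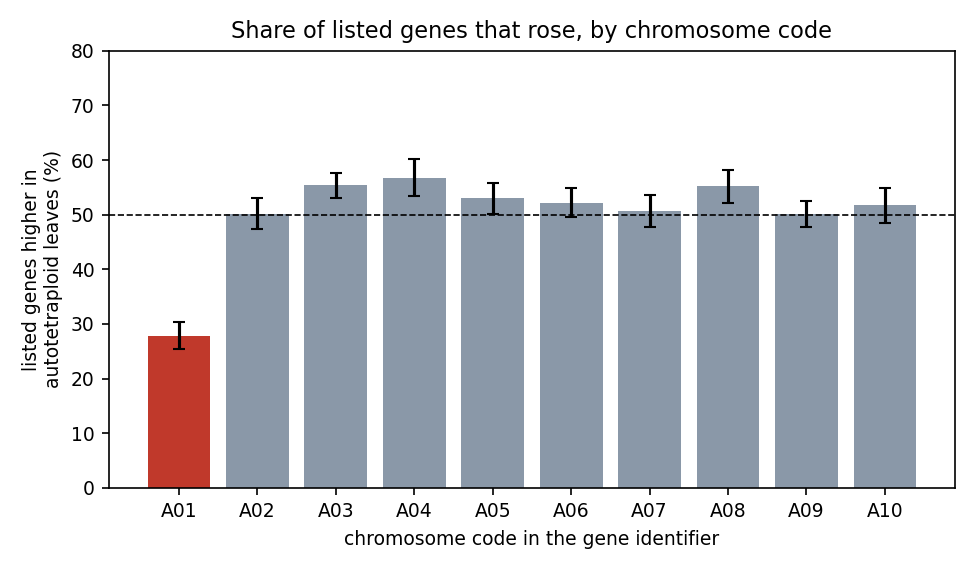
Share of listed genes that were higher in autotetraploid leaves (vertical axis, %) by the chromosome code in the identifier, with 95% Wilson intervals for counting error. A01 stands at 27.9%, and the other codes lie between 50.1% and 56.8%.

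Whether leaves of autotetraploid plants vary more between plants than those of doubled haploids could be examined only for weakly expressed genes. For 2590 genes with both means under 100, the reads of each library were worked back from the group means. The mean distance between libraries was 0.65 in the autotetraploid and 0.61 in the doubled haploid group on the log2 scale (exact permutation test, two-sided, p = 0.60). With 3 libraries against 3 this test cannot give a p below 0.1. The difference of 0.031 turned to -0.032 with quantile normalisation and was 0.121 with a pseudocount of 0.1, and the genes had all been listed for passing a test between the groups, which favours genes with little spread within a group.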

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

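The stricter limits, the subsets of genes, the minimum means of 20 and 100 and the use of genes with recovered reads were chosen after seeing the data; the pseudocounts, minimum mean of 5, quantile normalisation, models and set tests run on those reads had been planned for values of all genes. The planned scaling by median ratio, the correction for length and GC content, the protein motifs, and camera or limma on all genes were not run, since the table holds group means of listed genes and no gene models were used. No paired analysis was possible because the table holds group means and the recovered libraries carry no replicate number. The count of 13225 genes stayed within 1.5 times except with a Bonferroni limit, which left 6738 (3378 higher, 3360 lower). The 15 lists that passed became 8 with 1 gene per protein hit, all among the 15; the share that rose moved from 71.4% to 57.1% for histones and from 74.4% to 63.2% for pathogenesis-related genes, and the cause was not tested. Ribosomal, photosystem, carbon fixation, heat shock and NAC lists passed under all 6 subsets of genes. The direction turned for chromatin and DNA methylation genes among those changed at least 2-fold (72.2% rose, Fisher's exact test, adjusted p = 0.0489) and for auxin genes with a mean of at least 100 (31.9% rose), while auxin genes changed at least 2-fold passed the other way (59.0% rose); the cause was not tested. The A01 share that rose lay between 23.9% and 28.7% under 4 subsets of genes. The difference in spread between the groups, 0.031, turned to -0.032 with quantile normalisation (exact permutation p = 0.40) and was 0.121 with a pseudocount of 0.1 (exact permutation p = 0.1, the smallest this design allows, so that no setting could pass). On recovered reads limma called 2590 of 2590 genes, and 2557 to 2586 with a library left out, which says little since the genes were listed for passing a test. With camera 3 lists passed there (DNA replication, ribosomal and auxin genes), 0 with an estimated correlation, while fry called 22; the cause was not tested. Other splits of the 6 libraries are too few to exclude chance. The real split called 2590 genes against at most 0 in the other splits (1 of 10 as large) and 3 lists against at most 4 (3 of 10 as large). The gene counts were all but fixed in advance, since the genes had been listed for differing in the real split. They therefore say nothing about chance. Depth limits the smallest change that could be listed, at the 5th percentile 2.53-fold for means under 20 and 1.16-fold for means of at least 1000.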

Other observations

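The gene groups and tests in this part were chosen after the data were seen, while the tests on genes with the same protein hit, on autophagy genes and on genes changed at least 8-fold had their bounds set before their values were seen. Proteasome genes, which encode the main protein-degrading complex, rose in 30 of 34 cases (Fisher's exact test, adjusted p = 2.61e-05), and tRNA ligase genes in 22 of 26 (adjusted p = 0.00137, Fisher's exact test). Their median changes were small, at 1.27-fold and 1.39-fold. Small heat shock protein genes fell in 19 of 20 cases with a median of 11.5-fold, and heat stress transcription factor genes in 14 of 18, with a median of 4.84-fold. Chlorophyll breakdown genes went both ways, with 5 rises and 8 falls (Fisher's exact test, adjusted p = 0.548). Of these, named after their values were seen, STAY-GREEN 2 (evm.TU.BraA03002933) fell from 482 to 5.11 in the authors' deposited table. Genes matching STAY-GREEN 1 went both ways there. A rise from 247 to 452 (evm.TU.BraA08001500) stood beside falls from 2224 to 539 (evm.TU.BraA01001706) and from 996 to 701 (evm.TU.BraA03005404). Evening clock genes rose in 14 of 18 cases (adjusted p = 0.0571) and morning clock genes in 4 of 13 (adjusted p = 0.289, both Fisher's exact test), so neither list passed. Members of both went either way. Among evening genes, also named after their values were seen, ELF4 (evm.TU.BraA05003800) rose from 346 to 1521 in the authors' deposited table. Genes matching LUX, named likewise, went both ways there. Rises from 283 to 1267 (evm.TU.BraA01002149) and from 78.4 to 446 (evm.TU.BraA06000984) stood beside a fall from 678 to 189.5 (evm.TU.BraA03003700). A further LUX gene with low counts (evm.TU.BraA03000206) fell as well, with a log2 fold change of -1.87. Among morning genes CCA1 (evm.TU.BraA05004372) fell from 370 to 115 and LHY (evm.TU.BraA08003463) rose from 21.8 to 45.6 in the authors' deposited table.

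The A01 share of reads was taken over 456 genes with recovered reads, a chromosome code and a change under 2-fold. It lay between 7.80% and 8.10% in the autotetraploid and between 10.2% and 10.8% in the doubled haploid libraries. All 3 autotetraploid libraries thus lay below every other one. A single autotetraploid library is not excluded by this, since the genes were listed for a difference between the groups. Of all 2590 genes with recovered reads, 99.1% had no overlap between the groups, against 10% by chance, a share that the listing itself favours. Families regulated in a single direction do not explain all of the low A01 values of the 462 protein hits listed on A01 and elsewhere. There, A01 genes differed from genes elsewhere with the same hit by a median of -0.22 on the log2 scale (95% interval -0.30 to -0.14). For the other codes this median lay between -0.05 and 0.05, though the interval for A08 (0.011 to 0.115) did not hold 0 either. Families listed only on A01 were not examined, and families may still carry part of the fall. As a hypothesis, the autotetraploid plants may carry 3 copies of A01 for every 4 of the other chromosomes: the shift estimated for A01 was -0.38 (95% interval -0.47 to -0.31), which holds the log2 ratio of -0.42 for 3 of 4 copies and not the -0.58 for 2 of 3, while every other code lay between -0.06 and 0.07. The interval around the -0.22 from genes with the same hit does not hold that ratio, but the estimates are unlike measures. The -0.38 comes from genes with a mean of at least 500 and allows for the small changes left out. The -0.22 is a plain median over listed genes at all counts, so their difference does not decide the ratio. The intervals of both estimates come from redrawing genes or hits. They carry no spread between plants or libraries, so they cannot choose between copy numbers. Copy number was not measured and the identifier code was taken as the chromosome, so the hypothesis stays open.

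Ribosomal and photosynthesis genes rose while heat shock, NAC and abscisic acid genes fell. A single scaling offset moves all genes one way and so cannot be the whole cause of rises in some lists and falls in others. Ribosomal against NAC genes are an example (Fisher's exact test, p = 7.25e-35). The pair was picked after both lists were seen to differ, so this p only restates that difference. An offset beneath the ribosomal rise was not tested. That rise had a median of 1.35-fold, with 1.28-fold for 40S and 60S genes and 1.92-fold for chloroplast ones in lists added later. An older or more senescent leaf in the doubled haploid samples was put forward from SAG12. A share of rises among autophagy genes at or above that of the other described genes had been set beforehand as going against it. That bound was met, with 58.8% of 17 genes against 50.2%, but the shares could not be told apart (Fisher's exact test, p = 0.629). Chlorophyll breakdown genes leaned the other way, with rises in 38.5% of 13 (p = 0.422, Fisher's exact test), so this explanation stays open. Another hour of harvest may also be involved, since 30.8% of morning and 77.8% of evening clock genes rose (Fisher's exact test, p = 0.0130), but the evening list was reworded after its first wording, which took efflux carriers for clock genes, had given p = 0.209. No label gives the hour or the age of the leaf beyond the stage, so neither can be told apart from ploidy.

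For genes with a mean from 20 to 100 the median dispersion index was 1.12 in the autotetraploid and 1.03 in the doubled haploid group, near the 1.06 and 1.07 that a variation of 10% between libraries gave in simulations, where read sampling alone gave 0.688 and 0.693 and a variation of 20% gave 2.05 and 2.16. Selection of genes by a small p could lower this spread, and the index of genes changed at least 8-fold differed from that of all genes by up to 0.227, which leaves it undecided. Libraries made from a single pool of plants or a single extraction could give such a spread too, and the index of 1.12 does not decide it, since the labels call the libraries biological replicates and say no more.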
